A study of Mus musculus with 6 samples.

How the data were processed

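RNA from mouse dental pulp was measured on 6 Affymetrix mouse expression arrays, 3 control and 3 Ring1 deletion, each labelled as a biological replicate. Per the labels' protocols, total RNA was purified on micro columns, treated with DNase, amplified as cDNA with a kit for picogram amounts, amplified again by in vitro transcription and labelled with biotin. Each such step can compress or skew levels, and less intact RNA is read mainly near its 3' end, so 3' to 5' ratios of control probe sets were examined. Groups and replicate numbers were taken from the sample titles, and the dose and days from the treatment text in the labels.

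Per the submitters' processing notes the software was MAS5, which turns perfect match and mismatch probes into one signal per probe set and a Present, Marginal or Absent call. The deposited signals are probe set intensities on a linear scale that the authors made with MAS5. These authors' signals had a mean of 500 on each array after trimming 2% at each end, as found from the values, so the arrays were already scaled to one level. MAS5 signals of undetected probe sets scatter widely on a log scale, which inflates fitted fold changes against an undetected group. The detection calls came from a deposited workbook whose column names give the group but not the replicate, so calls were counted per group, and 12 further workbook columns of per-sample values were not used here. The array software version, scan dates and genome build were not given in the sources used here, and no coordinates are printed.

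Probe sets were named from the platform annotation supplied for the array, which can be old: 34958 probe sets had 1 gene symbol, 932 had several and 9211 none, 64 probe sets being controls of the array. Entrez identifiers of 34754 probe sets matched a current RefSeq gene table, and no symbol had to be altered. Probe sets with 1 symbol and a Present call on at least 3 of the 6 arrays were kept (21614), and each gene was represented by its kept probe set with the highest mean log2 signal, giving 12250 genes. Among the 158 named genes 65 had more than 1 kept probe set, and a probe set of opposite sign occurred in 4, Higd1a, Nfatc1, Rps6 and Rsad2, none of which passed the test.

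Signals under 1 were set to 1 and log2 was taken, with no further normalization. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All adjusted p of single genes come from this fit. A group in which a gene had no Present call gives only a bound. Its level on each array was then taken as the higher of the gene's signal and the lowest signal on that array among probe sets Present on all 3 arrays of its group, and the ratio of the group means of log2 values is given as at least N-fold. That lowest signal ranged from 10.5 to 15.5 over the arrays, and a higher floor would give lower folds for signals under it. Where the signals of the undetected group lay above it, the value printed is the fitted fold, with no allowance for its error.

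The 37 gene lists, fixed before the data were examined, held 939 different genes, of which 694 were tested. Lists were tested against all other genes with camera (preset correlation of 0.01, Benjamini-Hochberg over the 37 lists), and again with an estimated correlation. Of 10 lists that passed, 2 passed with an estimated correlation, Hox genes and developmental transcription factors outside the Hox clusters. The latter list had an estimate of -0.0109, below the preset value, yet its unadjusted camera p went from 9.61e-19 to 0.000477. A call lost in that run is therefore not shown to be lost through correlation between genes. The intensity trend in camera's variance was not part of the fixed design: without it 9 lists passed, and it was set to match the gene test after that count was known. Genes were named by a rule fixed before the data were examined: the targeted genes, the 10 with the largest rise and the 10 with the largest fall among changed genes whose groups do not overlap, a fixed set of cell cycle, Wnt, Hedgehog and odontoblast genes, and up to 4 members with the smallest p in each list. Genes named outside it are said to be chosen after their values were seen.

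Replicate numbers in the titles run from 1 to 3 in each group. The deviations of same-numbered arrays from their group means correlated at 0.485, 0.189 and 0.286 for replicates 1, 2 and 3. All were over 0.1, and by that cut the numbers were treated as pairing the arrays in an alternative fit. Control replicate 3 with deletion replicate 2 gave 0.213, and control replicate 2 with deletion replicate 3 gave 0.117. Beyond the replicate 1 arrays the values thus do not show a pairing. The main calls come from the fit without the block. The values with the replicate block are printed where they change a call or move a count by over 1.5-fold. Alternatives covered normalization, low signals, the detection filter, the variance model, the choice of probe set, the threshold, the set test, each array left out and the replicate block. The replicate 1 arrays and the other 4 as batches, the replicate 1 arrays left out and the set tests with the block were added after the data were seen, since the replicate 1 arrays stood apart on the second principal component and in their 3' to 5' ratios.

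The fit was tested on 20 simulated data sets of 12250 genes each with 200 changed genes for the comparison of deletion with control. It recovered 31.6% of genes changed 2-fold and 80% of those changed 4-fold, and 4.7% of its calls were false. The simulated noise was independent between genes and between arrays, without replicate or batch differences. These shares are therefore not the error rates of the real calls. Among random lists of independent unchanged genes 1.17% had a camera p under 0.05, a figure that does not cover correlated genes. Probe sets without a single gene name stayed out of the gene test, and no raw array scans were used here. Figures were drawn with matplotlib 3.10.9.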

Results

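Transcript levels were measured on 6 Affymetrix expression arrays hybridised with RNA from mouse dental pulp, 3 from control mice and 3 from mice with a Ring1 deletion. The incisor of the mouse grows throughout life, and the series title places the experiment in the passage of its mesenchymal stem cells to transit amplifying cells. Ring1a (gene symbol Ring1) and Ring1b (gene symbol Rnf2) are E3 ligases that place ubiquitin on histone H2A within Polycomb repressive complex 1. All 6 samples were labelled as lacking Ring1a and carrying floxed Ring1b with a tamoxifen-inducible Cre recombinase. The deletion mice received 40 mg/kg 4-hydroxytamoxifen at postnatal days 9 and 13, the control mice received corn oil, and pulp was taken at day 17. Drug and deletion therefore differed together between the groups. Between 53.8% and 57.9% of the 45101 probe sets were called Present per array. Each array is labelled as a biological replicate, so p-values measure the spread between these replicates.

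The transcript of the targeted gene was not lower on the arrays labelled Ring1 deletion. The probe set used for Rnf2 had a mean log2 signal of 11.26 ± 0.14 in control and 11.63 ± 0.16 in deletion (SD, n = 3). This was a difference of 0.37 ± 0.17 (SE) on the log2 scale, or 1.29-fold, that did not pass the test (limma adjusted p = 0.33). A further Rnf2 probe set called Present on every array differed by 0.53 ± 0.18 on the log2 scale, with deletion higher. The other 3 Rnf2 probe sets and the Ring1 probe set were called Present on no array. Where these probe sets lie relative to the deleted part of Rnf2 was not known here, so their values do not check the labels.

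Genes that pattern the embryo, many of them Hox genes, took most of the highest places by fitted change among the genes that rose in the deletion arrays. Among cell division genes, 15 of 44 of G2/M and mitosis and 9 of 41 of G1/S and DNA replication fell, but neither list passed with an estimated correlation between genes (adjusted p = 0.33 for both). Of 12250 genes tested, 325 changed at an adjusted p under 0.05, of which 232 rose and 93 fell, so 71.4% of the changed genes were higher in deletion. The median log2 change was 1.60 among the genes that rose and -1.51 among those that fell, and 208 and 86 of them changed at least 2-fold. For 44 of the risen genes no control array had a Present call, and 6 of the fallen genes were Present on no deletion array. In all 325 genes the 3 deletion arrays lay on one side of the 3 control arrays, a separation that 2551 genes (20.8% of those tested) showed, against the 10% that chance gives. That 10% holds if the 6 arrays are interchangeable, with no pairs or batches among them. With the replicate number as a block in the fit, 1302 genes changed (789 higher, 513 lower). The count was 94 without control replicate 2, 148 without deletion replicate 3, 188 without control replicate 3 and 196 without deletion replicate 2, and a test without variance moderation called 1 gene. The balance of directions moved as well, from 54.1% higher without deletion replicate 2 (106 of 196) to 87.2% without control replicate 2 (82 of 94).

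**Figure D1:**
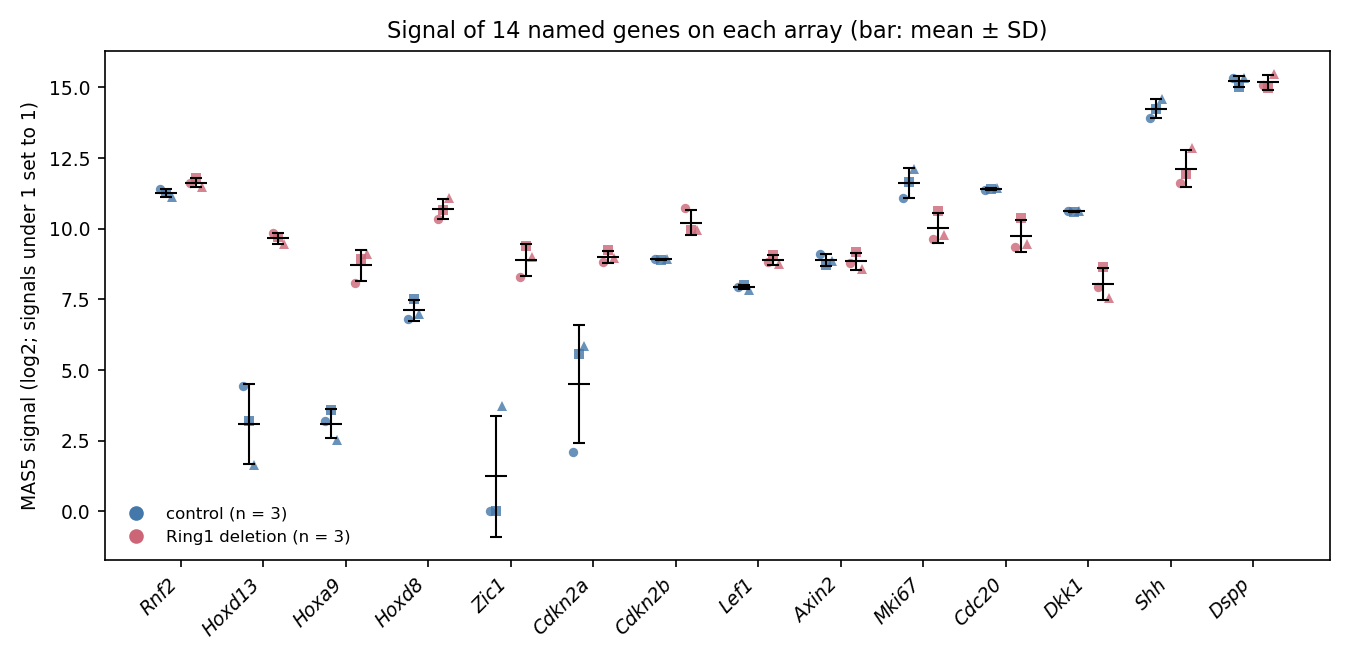
Log2 MAS5 signal (y axis, signals under 1 set to 1) of 14 named genes (x axis) on the 3 control arrays (blue) and the 3 Ring1 deletion arrays (red). Circles, squares and triangles are replicates 1, 2 and 3, and bars give the mean and SD of each group; Hoxd13 averaged 3.10 in control and 9.67 in deletion, while Dspp averaged 15.21 and 15.18.

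Most of the genes with the largest fitted rise encode transcription factors that pattern the embryo; fits over undetected signals overstate a fold, and the bounds rank these genes in another order. Zic1, a zinc finger factor of neural and somite development, was at least 37.2-fold higher in deletion (log2 signal 1.24 ± 2.14 in control and 8.89 ± 0.56 in deletion, SD, n = 3). Hoxd13, a factor of the distal limb, was at least 51.9-fold higher, Hoxc8 at least 44.7-fold, Hoxc9 at least 33.2-fold, Hoxa9 at least 32.7-fold and Hoxa10 at least 25.0-fold. Tbx18 was at least 27.1-fold higher and Sox1, a marker of neural progenitors, at least 11.5-fold. Igf2bp1, an RNA-binding protein of fetal tissue, was at least 14.7-fold higher. These 9 genes were called Present on all 3 deletion arrays and on no control array, so each fold is a bound that holds only for the floor used. For Hoxc8 and Hoxc9 it equals the fitted fold (44.71 and 33.23). Their adjusted p ranged from 0.00109 for Hoxc8 to 0.00822 for Igf2bp1 in limma. Meis2, a cofactor of Hox proteins, was Present on 1 control array and differed by 4.93 ± 1.02 (SE) on the log2 scale (limma adjusted p = 0.04).

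Of 33 Hox genes named on the array, 15 were tested, 10 of them rose and none fell, and all 15 were higher in deletion; adjusted over the list alone, 15 rose. Of the 33 Hox genes, 30 had no Present call in control and 9 had none in deletion, whereas 1 was Present on all 3 control arrays and 15 on all 3 deletion arrays. A gene with no Present call in control was tested only if Present on all 3 deletion arrays. Most of the tested members thus entered through the group where they were high. The direction counts, median and camera p of the list rest in part on that selection. The member measured in both groups, Hoxd8, rose by 3.59 ± 0.26 (SE) on the log2 scale, or 12.0-fold (limma adjusted p = 0.00109). The median log2 change of the list was 4.27, or 3.80 with genes below detection at their bounds, and it was 4.89 between the replicate 1 arrays and 3.85 between the other 4. Camera, limma's competitive set test with a preset correlation between genes, gave the Hox list an adjusted p of 3.97e-23, and with an estimated correlation the adjusted p was 0.0468. With an estimated correlation and the replicate block the list did not pass (adjusted p = 0.198).

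Of 40 tested developmental transcription factors outside the Hox clusters, 16 rose and none fell, with a median log2 change of 0.98, and 22 rose when adjusted over the list alone (camera adjusted p = 1.18e-17, and 0.0176 with an estimated correlation, but 0.198 with an estimated correlation and the replicate block). The number that rose was 8 without deletion replicate 2 or deletion replicate 3. Of the 68 members named on the array, 38 had no Present call in control and 21 had none in deletion. Detection in deletion therefore selected part of this list as well. Zic5, Present on 1 control array, differed by 4.39 ± 0.42 (SE) on the log2 scale, with control signals between 10.89 and 27.43. Zic2 was at least 10.1-fold higher. Tbx15 was at least 8.12-fold higher, and Sox1, Tbx18, Zic1 and Meis2 belong to the same list. Core components of the Polycomb complexes were measured beside these genes: none of 24 changed (2 rose with the replicate block), and their median log2 change was 0.09 (camera adjusted p = 0.537). Bmi1, a subunit of Polycomb repressive complex 1, had a difference of 0.62 ± 0.18 (SE) with deletion higher and did not pass (limma adjusted p = 0.12, and 0.0195 with the replicate block).

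Genes of mitosis were lower in the deletion arrays. Of 44 genes of G2/M and mitosis, 15 fell and none rose, all 44 had lower means in deletion, and the median log2 change was -1.36; adjusted over the list alone 40 fell, and 40 fell with the replicate block. Bub1b, a kinase of the spindle checkpoint, fell by 1.75 ± 0.23 (SE) on the log2 scale, the cytokinesis factor Ect2 fell by 1.86 ± 0.26, and Cdc20, an activator of the anaphase-promoting complex, fell by 1.67 ± 0.26. Mki67, the proliferation marker Ki-67, had 0.332 times the control signal (log2 11.62 ± 0.52 in control and 10.03 ± 0.54 in deletion, SD, n = 3; limma adjusted p = 0.0355). The count of members that fell was 2 without control replicate 2, 5 without control replicate 3, 4 without deletion replicate 3 6 without deletion replicate 1 and 23 without deletion replicate 2; it was 6 without an intensity trend, 8 with the mean of probe sets and 38 with array quality weights. Camera gave an adjusted p of 8.48e-33, against an adjusted p of 0.33 with an estimated correlation. Esco2, which joins sister chromatids, was among the 10 genes that fell most (-2.56 ± 0.36, SE; limma adjusted p = 0.00863).

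Genes of G1/S and DNA replication were also lower. Of 41 tested, 9 fell and none rose, the median log2 change was -0.81, and 23 fell and 1 rose when adjusted over the list alone (22 and 1 with the replicate block). Mcm5, a subunit of the replicative helicase, fell by 1.51 ± 0.25 (SE) on the log2 scale, Rrm2 of ribonucleotide reductase fell by 1.47 ± 0.28, Uhrf1 fell by 1.80 ± 0.35 and E2f8 fell by 1.76 ± 0.33. The camera adjusted p was 1.38e-17, and the adjusted p was 0.33 with an estimated correlation. Without control replicate 2, or without control replicate 3, 0 of the 41 passed, and 1 passed without deletion replicate 1 or without deletion replicate 3; 2 passed without an intensity trend and 20 with array quality weights. Ccnd1, encoding cyclin D1, differed by 0.28 ± 0.24 (SE) with deletion higher and did not pass (limma adjusted p = 0.669). Beside both cell cycle lists, markers of dental epithelium had a median log2 change of -0.75 between the replicate 1 arrays and 0.19 between the other 4, while the mitotic median was -1.40 and -1.29.

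Among 7 cyclin-dependent kinase inhibitors, 3 rose and none fell, and 3 rose and 3 fell when adjusted over the list alone. Cdkn2a, whose locus encodes p16 and p19ARF, was Present on no control array and was at least 16.1-fold higher in deletion (limma adjusted p = 0.0271). Its neighbour Cdkn2b, encoding p15, rose 2.46-fold (log2 8.92 ± 0.01 in control and 10.22 ± 0.44 in deletion, SD, n = 3; limma adjusted p = 0.0227). Cdkn1c, encoding p57, rose 1.96-fold (limma adjusted p = 0.0264). Cdkn1a, encoding p21, went the other way with a log2 difference of -0.62 ± 0.21 (SE) and did not pass (limma adjusted p = 0.191). The test of the 7 as a list showed no common direction (camera adjusted p = 0.701), with a median of -0.33 and a mean of 0.70. Of 20 p53 target genes, 1 rose, Phlda3, by 0.99 ± 0.20 (SE) on the log2 scale; the camera adjusted p was 0.0472 toward higher values, and the adjusted p was 0.33 with an estimated correlation. Without control replicate 1 the camera adjusted p of this list was 0.128, and the call also ended without deletion replicate 2 (0.0799) or deletion replicate 3 (0.0796), with array quality weights (0.0699), without an intensity trend (0.0617) and among genes Present on all 6 arrays (0.0708). It ended as well without both replicate 1 arrays (camera adjusted p = 0.0876). Of 13 secreted factors linked to senescence, Igfbp5 and the chemokine Ccl7 rose, and the list did not pass (camera adjusted p = 0.0575). Without both replicate 1 arrays it passed toward higher values (camera adjusted p = 0.0208). With the replicate block 4 p53 targets and 4 senescence factors rose.

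**Figure D2:**
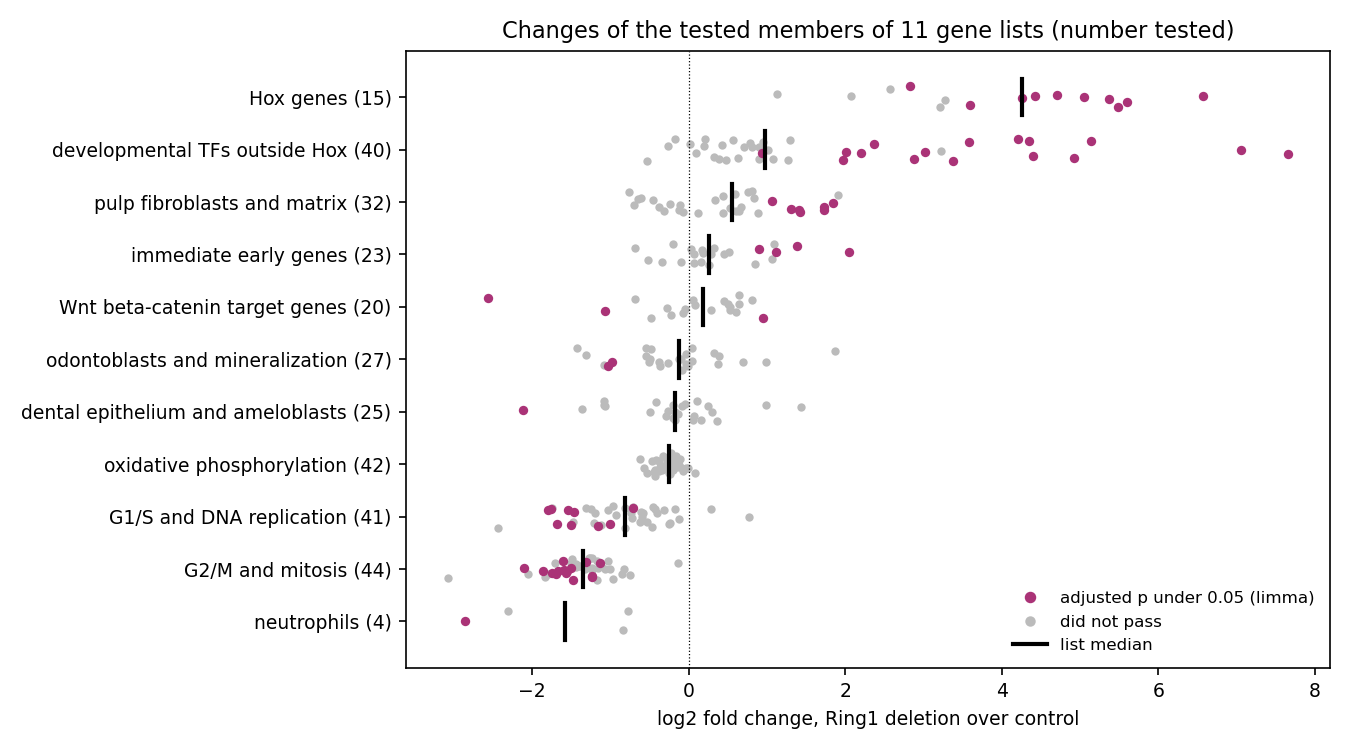
Log2 fold change of deletion over control (x axis) of each tested member of 11 gene lists (rows, with the number tested). Purple points passed the limma test at an adjusted p under 0.05, grey points did not, and black lines mark list medians, which run from 4.27 for Hox genes to -1.58 for neutrophil markers.

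Genes of Wnt signalling moved in both directions. Dkk1, a secreted Wnt inhibitor and target, had a log2 signal of 10.61 ± 0.01 in control and 8.05 ± 0.57 in deletion (SD, n = 3), a 5.93-fold difference (limma adjusted p = 0.00431). Notum, a secreted enzyme that inactivates Wnt proteins, fell by 1.07 ± 0.23 (SE) on the log2 scale (limma adjusted p = 0.0448). Sfrp1, another secreted antagonist, rose 2.81-fold (limma adjusted p = 0.017), and Lef1, a transcription factor of the pathway, rose 1.93-fold (limma adjusted p = 0.0429). Axin2, a direct target of beta-catenin, showed a log2 difference of -0.05 ± 0.22 (SE; limma adjusted p = 0.953). Of 20 beta-catenin target genes 1 rose and 2 fell, and the list did not pass (camera adjusted p = 0.653). Of 14 secreted antagonists 1 rose and 2 fell, with a median of 0.33 and a mean of -0.04 (camera adjusted p = 0.653). The 2 that fell were Dkk1 and Notum in both lists, so they are not separate evidence. Of 29 Wnt ligands and receptors, Fzd9 rose, by 1.24 ± 0.25 (SE) on the log2 scale, and the list did not pass (camera adjusted p = 0.653); with the replicate block 6 of these rose and 5 fell, against 4 and 2 of the beta-catenin targets and 3 and 3 of the antagonists.

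Shh, a signal that the dental epithelium sends to the pulp, fell 4.34-fold (log2 14.25 ± 0.34 in control and 12.13 ± 0.64 in deletion, SD, n = 3; limma adjusted p = 0.00931). Transcripts of ameloblasts, the enamel-forming cells of that epithelium, were abundant in both groups. Of 25 epithelial genes, Shh alone changed, and the list did not pass (camera adjusted p = 0.0962); 2 rose and 4 fell with the replicate block. Amelx, the main enamel matrix gene, chosen after its values were seen, had a log2 signal of 15.50 ± 0.37 in control and 14.14 ± 1.55 in deletion (SD, n = 3; limma adjusted p = 0.349). Gli1, a target of Hedgehog signalling, had a log2 difference of -0.65 ± 0.25 (SE) that did not pass (limma adjusted p = 0.241, and 0.0397 with the replicate block). Among 14 Hedgehog pathway genes none but Shh changed (camera adjusted p = 0.393), and with the replicate block 6 rose and 2 fell.

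Few genes passed in the lists of other growth factor pathways. Ltbp1 and Tgfbr3 of the BMP and TGF-beta list rose 2.57-fold and 2.34-fold (limma adjusted p = 0.015 and 0.0236), the only changes among 25 members, and the list did not pass (camera adjusted p = 0.841, median -0.03, mean 0.13). Fgfr2 rose 2.44-fold, the only change among 17 FGF pathway genes (camera adjusted p = 0.0995). Without both replicate 1 arrays the FGF list passed toward lower values (camera adjusted p = 0.0193). None of 17 Notch pathway genes changed (camera adjusted p = 0.608, median 0.05, mean -0.04). Fst, the activin antagonist follistatin, had a difference of 1.71 ± 0.40 (SE) with deletion higher (limma adjusted p = 0.0618, and 0.000344 with the replicate block). With that block 4 BMP and TGF-beta genes rose and 1 fell, 2 FGF genes rose and 2 fell, and 1 Notch gene rose and 1 fell.

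Of 32 fibroblast and matrix genes of the pulp 7 rose and none fell, 21 had higher and 11 lower means in deletion, with a median log2 change of 0.56; adjusted over the list alone 15 rose and 3 fell, and the replicate block gave the same counts. Thbs2 and Loxl1 each rose 3.30-fold, Igfbp5 rose 2.68-fold and Ogn 2.66-fold. The camera adjusted p was 0.000113, and the adjusted p was 0.33 with an estimated correlation. Without control replicate 2 the number that rose was 2. Of 27 odontoblast and mineralization genes, Tubb3 fell 2.04-fold and Col24a1 fell by 0.97 ± 0.18 (SE) on the log2 scale, and with the replicate block 3 rose and 6 fell. Dspp, the dentin matrix gene that marks odontoblasts, had a log2 signal of 15.21 ± 0.19 in control and 15.18 ± 0.27 in deletion (SD, n = 3; limma adjusted p = 0.958). The odontoblast list had a camera adjusted p of 0.0414 toward lower values with a median of -0.13, and an adjusted p of 0.336 with an estimated correlation. That call was lost without control replicate 1 (camera adjusted p = 0.224), without deletion replicate 2 (0.0716) or deletion replicate 3 (0.0907), and under quantile normalization (0.248), median centring (0.053), the mean of probe sets (0.06), array quality weights (0.0665) and a filter for Present calls on all 6 arrays (0.0864). Without both replicate 1 arrays the odontoblast list did not pass either (camera adjusted p = 0.105). With any 1 of the control arrays left out, 0 members passed.

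Genes tied to the stem cells of the incisor gave few calls. Prrx1, a mesenchymal homeobox gene, rose 2.21-fold (limma adjusted p = 0.0114), and Alcam, a surface protein of mesenchymal progenitors, rose 2.71-fold (limma adjusted p = 0.0448). They were the only changes among 20 stem cell-associated genes, of which 14 were higher in deletion (camera adjusted p = 0.0962, and 0.0344 with the replicate block, where 7 rose and 4 fell). Among 27 transcription factors of dental mesenchyme Prrx1 alone changed (camera adjusted p = 0.0962), and with the replicate block 6 rose and 1 fell. Lhx8 had a difference of -1.17 ± 0.28 (SE; limma adjusted p = 0.0671, and 0.00131 with the replicate block), and Acta2, a mural and progenitor marker, one of -0.86 ± 0.19 (limma adjusted p = 0.0512, and 0.00266 with the block).

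Markers of blood and immune cells were measured because dissected pulp holds vessels. S100a9, a neutrophil protein, fell by 2.87 ± 0.49 (SE) on the log2 scale (limma adjusted p = 0.0188), and all 4 tested neutrophil genes were lower in deletion, with a median of -1.58, which was -2.96 between the replicate 1 arrays and -1.02 between the other 4. The list's camera adjusted p was 0.00109, and the adjusted p was 0.33 with an estimated correlation. With the replicate block 2 of the 4 fell. S100a9 lost its call without control replicate 2 or deletion replicate 2. Hbb-b2 was at least 14.5-fold lower in deletion (limma adjusted p = 0.0132), but globin genes are near copies of one another and a probe set can read several, and Tspan33 rose among the same 4 erythroid genes (camera adjusted p = 0.398). No member changed among 22 endothelial, 13 mural, 27 macrophage, 8 osteoclast, 5 lymphocyte, 10 Schwann cell and 5 skeletal muscle genes, and camera adjusted p for these lists lay between 0.113 for osteoclasts and 0.771 for skeletal muscle. With the replicate block 6 macrophage genes rose and 1 fell, 4 mural genes rose and 2 fell, 1 osteoclast gene rose and 1 lymphocyte gene fell. Uchl1 and Ina, cytoplasmic and filament proteins of neurons, rose 2.37-fold and 4.43-fold among 10 neuronal markers (camera adjusted p = 0.0922), of which 3 rose and 1 fell with the block. Col2a1, the collagen of cartilage, was Present on no control array and at least 10.7-fold higher in deletion (limma adjusted p = 0.0017), the only change among 8 cartilage genes (camera adjusted p = 0.0922, and 0.0473 with the replicate block, where Col9a1 and Col9a2 also passed, with block adjusted p of 0.00131 and 0.00544).

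Stress and metabolic genes made up the remaining lists. Of 23 immediate early genes Ccn1 rose 4.13-fold, the heat shock genes Hspa1b and Hspa1a 2.60-fold and 2.16-fold, and Jun 1.86-fold. Hspa1a and Hspa1b are near-identical copies, so their probe sets may not tell them apart. The list had a camera adjusted p of 0.0122 toward higher values, and an adjusted p of 0.41 with an estimated correlation. With the replicate block 7 rose and 2 fell. Without deletion replicate 1 its camera adjusted p was 0.101, and leaving out any array but control replicate 1 left 2 members called. None of 42 oxidative phosphorylation genes changed, 41 of them had lower means in deletion, and their median log2 change was -0.25, or -0.54 between the replicate 1 arrays and -0.13 between the other 4 (camera adjusted p = 1.99e-06; adjusted p = 0.467 with an estimated correlation). Slc2a3, a glucose transporter, rose 2.46-fold, the only change among 22 glycolysis and hypoxia genes (camera adjusted p = 0.393). None of 20 interferon-stimulated genes (camera adjusted p = 0.6), 10 estrogen-responsive genes (0.293) or 26 cytosolic ribosomal protein genes (0.131) changed. With the replicate block 2 glycolysis and hypoxia genes rose and 2 fell, 4 estrogen-responsive genes rose and 1 fell, 1 ribosomal protein gene rose and 1 oxidative phosphorylation gene fell.

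Of the genes that fell most, several have no list. Krt27, a keratin of the hair follicle, was at least 17.4-fold lower in deletion, and Nr0b1, a nuclear receptor, at least 9.81-fold lower (limma adjusted p = 0.00641 and 0.0217). Ctnna2, a neural catenin, fell by 3.80 ± 0.41 (SE) on the log2 scale, and Lemd1 was at least 6.35-fold lower. Idi1, an enzyme of isoprenoid and cholesterol synthesis, fell by 2.35 ± 0.35 (limma adjusted p = 0.0106).

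**Figure D3:**
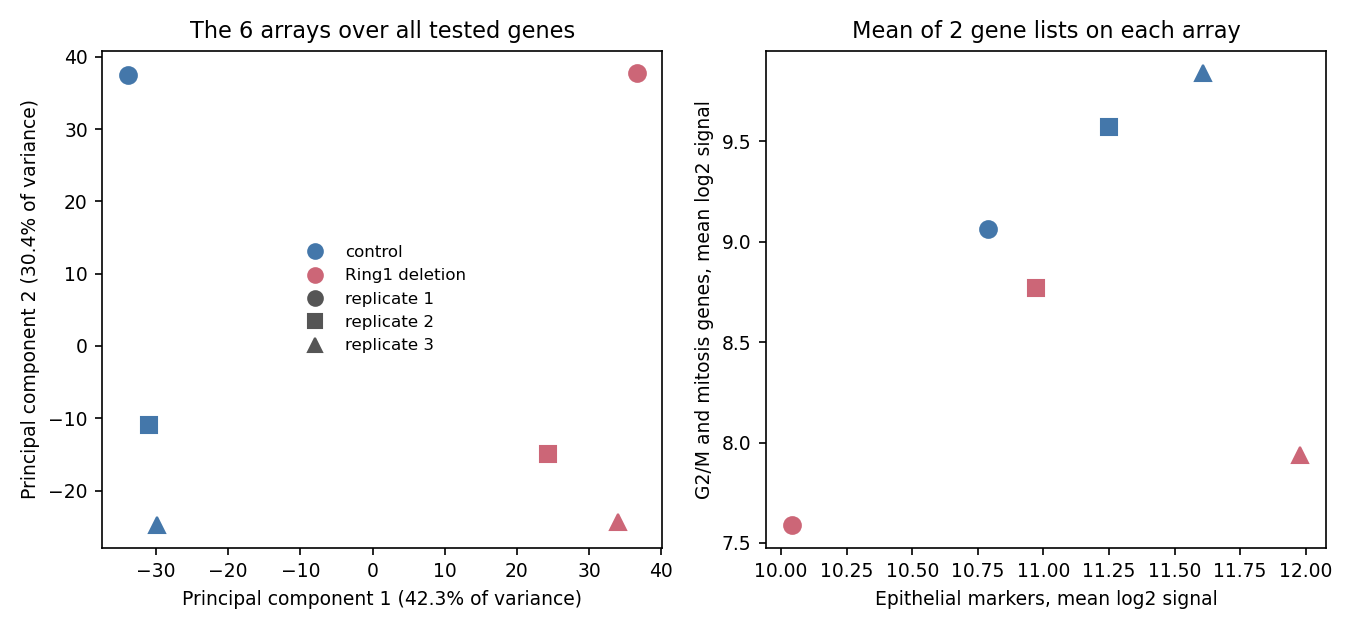
Left, the 6 arrays on the principal components of all tested genes (axes in component scores), with component 1 taking 42.3% and component 2 taking 30.4% of the variance. Right, the mean log2 signal of epithelial markers (x axis) against that of G2/M and mitosis genes (y axis) on each array; control is blue, deletion is red, circles, squares and triangles are replicates 1, 2 and 3, and the deletion arrays lie between 7.59 and 8.77 on the mitotic axis against 9.06 to 9.84 for control.

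The arrays separated by group along the first principal component, and along the second component the replicate 1 arrays stood apart from the other 4. Correlations between arrays over the tested genes lay between 0.943 and 0.978 within groups and between 0.914 and 0.952 between groups; they are across genes, which are not independent replicates. The 3' to 5' signal ratio of the Gapdh control probe sets, a sign of RNA length, was 1.62 (log2) on control replicate 1 and 0.39 on deletion replicate 1, and lay between -0.31 and -0.21 on the other 4 arrays. Its group difference was -0.40, deletion minus control (exact two-sided permutation p = 0.8, where 0.1 is the smallest possible), and 0.227 without control replicate 1; that of Actin was -0.25 (exact permutation p = 0.9). Such a test cannot show a difference with 3 arrays per group.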

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

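One result came from probe sets outside the gene test. Among probe sets without a single gene name, 49 were called Present on all 3 deletion arrays and on no control array, against 20 the other way round. Among the tested genes these counts were 122 and 52, so the skew is not particular to unnamed probe sets. Of the 4100 such probe sets that were kept, 47 changed, 39 higher and 8 lower in deletion (limma, Benjamini-Hochberg over all kept probe sets). Which genes they read was not analysed here.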

How the results depend on the processing

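The alternatives named as added were chosen after the data were seen. Against 325 changed genes in the main fit, 1302 changed with the replicate block, 1209 with the replicate 1 arrays and the other 4 as batches (added), 1106 with array quality weights (weights from 0.416 to 4.31, the highest for control replicate 2), 605 at an adjusted p under 0.1, 1423 at an unadjusted p under 0.05 and 1.5-fold, 500 without both replicate 1 arrays (added), 204 among genes Present on all 6 arrays, where fewer genes were tested, and 1 without variance moderation. Leaving out 1 array gave 94 (without control replicate 2) to 300 genes, with 188 without control replicate 3, 196 without deletion replicate 2 and 148 without deletion replicate 3. The cause of these shifts was not tested. Other settings gave 240 to 376 genes. The planned run on the workbook's signals is left out, as its columns name no replicate. Of 62 called named genes, between 25 (without control replicate 2) and 62 stayed called, and all that were still tested kept their direction. Other scalings moved the median of all genes by under 0.1 and gave 61.8% to 64.7% of calls higher.

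Against 10 lists in the main test, 2 passed with an estimated correlation, 0 with an estimated correlation and the replicate block (added), where Hox genes had an adjusted p of 0.198, and 6 with fry and the block (added), and 7 to 13 under the other settings. Fry also passed 10, all higher, but only 4 of the 10 in the main test: G2/M and mitosis (0.0593), G1/S and DNA replication (0.063), neutrophils (0.0593), odontoblasts (0.132), immediate early genes (0.0862) and oxidative phosphorylation (0.197) lost their call. In their place fry passed dental mesenchyme transcription factors (fry adjusted p = 0.00817). It also passed Polycomb components, Wnt ligands and receptors, osteoclasts, neurons and senescence factors (fry adjusted p = 0.0468 each). The replicate block changed no other call of the 37 lists than those given with the results. Without both replicate 1 arrays (added) the lists of stem cell-associated genes (camera adjusted p = 0.0401) and cartilage (0.0392) passed too. Signal over background limits the Hox result: among genes Present on all 6 arrays, 1 Hox gene was tested and called, and 1 developmental transcription factor outside the clusters was called, from 16.

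The named genes that reversed had not passed the test. Of all changed genes, Tubb4b turned under the mean of a gene's probe sets (from -1.04 to 0.0101) and Cacna1d without probe sets ending in _x_at or _s_at (from 1.12 to -0.0422), both named after their values were seen. With array quality weights the log2 difference was 0.0981 for Axin2, 0.104 for Dspp and 0.0657 for Myh1. Without both replicate 1 arrays (added) it was 0.0863 for Axin2, -0.036 for Ccnd1, 0.0614 for Dspp and 0.357 for Myh1. Quantile normalization gave 0.0347 for Dspp. The mean of a gene's probe sets gave -0.088 for Nfatc1 and 0.041 for Rps6. With no detection filter, and with a signal of at least 100 on 3 arrays, Ighm was at 0.0527 and Mal at 0.0928. With single arrays left out, Axin2 ran from -0.209 to 0.0776, Dspp from -0.191 to 0.0665, Ltb from -0.427 to 0.0317, Hba-a2 from -1.41 to 0.158, Myl1 from -0.211 to 1.1, Myh1 from -1.03 to 0.152, Mylpf from -0.383 to 0.103 and Col11a2 from -0.735 to 0.0601. The cause was not tested.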

Other observations

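Further gene groups were written down after the changed genes had been seen, so each was tested also without the called genes that prompted it. Leaving those genes out biases the test on the others against the direction seen, and keeping them biases it toward that direction. A failure of the others is thus no evidence against a list, and a pass with all members is none for it. The tests on these lists, on epithelium, on cartilage and on tissue from outside the tooth were chosen after their data were seen. So were those on the drug and on the arrays as batches behind the Hox genes. Imprinted genes, expressed from one parental copy, were mostly higher in deletion: of 36 tested, 7 rose and none fell, with a median log2 change of 0.40. Sfmbt2 rose 4.15-fold, the growth factor gene Igf2 3.12-fold, Zdbf2 2.85-fold and Grb10 2.54-fold (limma adjusted p = 0.00603, 0.00641, 0.0448 and 0.0181). Without the 7 that prompted the list the camera p was 0.00146 toward higher values, 0.0227 with an estimated correlation and 0.0682 with that and the replicate block, so a rise of the list as a whole stays open; with all 36 it was 5.7e-08, and 0.00364 with an estimated correlation. Leaving out 1 array moved the 0.0227 to between 0.0294 and 0.051. Genes of synapses and ion channels had 9 of 22 rising, among them Gnao1 (at least 4.91-fold), Nrxn2 (at least 4.61-fold) and Grm4 (3.70-fold). Another of the 9, Cacna1d, turned from 1.12 to -0.0422 without probe sets ending in _x_at or _s_at. Without the 9 that prompted the list the camera p was 0.0301, but 0.0834 with an estimated correlation and 0.207 with that and the block. A rise of this list stays open too (1.6e-09 and 0.00267 with all 22).

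Genes of cholesterol synthesis lay lower in deletion. Idi1 was the only one of 19 to pass the test, but all 19 had lower means, with a median log2 change of -0.49, among them Cyp51 (-1.16 ± 0.29, SE; limma adjusted p = 0.0778) and Sqle (-1.11 ± 0.28; limma adjusted p = 0.0776). Without Idi1 the camera p was 4.33e-07, but 0.0672 with an estimated correlation and 0.0312 with that and the replicate block, so a fall of the list stays open (3.31e-08 and 0.0614 with Idi1). Germline genes, 4 of which rose among 11 tested (Rbm46, Tcfl5, Cpeb1 and Ddx43), gave a camera p of 0.57 toward lower values without these 4, with a median of -0.23 (0.59 with an estimated correlation, 0.763 with that and the block), and 0.015 toward higher values with them (0.0633 with an estimated correlation). The 4 genes were left out because they rose, which biases the test on the others against a rise, so it cannot decide. Of all 12250 tested genes 232 rose.

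Risen genes lay next to one another along the chromosomes more often than random tested genes. With Hox genes left out, 30 of 219 risen genes with a known place had a risen gene as the next tested gene, against a median of 8 and a highest count of 25 in 10000 random draws (permutation p = 1e-04, the smallest the draws can give). The pairs include Zic5 with Zic2, Cdkn2a with Cdkn2b, Pantr1 with Pou3f3 and Ptx3 with Shox2. Some of them, such as Hspa1b with Hspa1a, are near copies and so not independent, and gene order was taken from a current RefSeq table. Of 93 fallen genes, 4 had a fallen gene as a neighbour, against a median of 2 and a highest count of 12 in random draws (permutation p = 0.15).

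The count of 325 changed genes stood against at most 1 gene in the other splits of the 6 arrays into 3 and 3, and 1 of the 10 splits, the real one, gave as many. For the 10 lists that passed, another split gave 12, and 2 of the 10 splits gave at least as many, so camera with a preset correlation passed lists also where arrays of both groups were mixed. That split set control replicates 1 and 3 with deletion replicate 3 against the rest, and so parted only 1 replicate pair. The other splits that part all 3 pairs, as the real one does, gave 7, 9 and 7 lists and 0 genes. With 10 splits a share under 0.05 cannot be reached for either count.

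The rise of Hox genes and other developmental transcription factors may come from the logarithm of signals near zero. With signals under 32 set to 32, 24 of the 26 called members stayed called, while their median change shrank from 4.31 to 3.02. That floor sets all control signals of genes such as Sox1, Zic1 and Hoxa9 to 1 value, removing spread and favouring a call. The count is therefore weak evidence against this source. The median of the 55 tested members lay above that of all genes by 1.96 within the replicate 1 arrays and 2.02 within the other 4. Part of the members were tested only because they were Present on all 3 deletion arrays, which favours a rise within both. These medians therefore cannot decide whether the replicate 1 arrays or the other 4 carried the rise. Hoxd8, Present on every array, differed by 3.54 within the replicate 1 arrays and 3.61 within the other 4. Muscle, cartilage or blood from outside the tooth stays open: list medians were at most 0.189, but members went both ways, several were well expressed in control, and Col2a1 rose by at least 3.42 on the log2 scale. The deletion and the drug, given together, also stay open and were not tested apart.

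The fall of mitotic genes was not carried by the replicate 1 arrays or by the other 4 alone, since the smaller of the within-batch differences between the mitotic median and that of all genes was -1.31. A smaller share of dividing dental epithelium in the deletion arrays could contribute. The epithelial list fell less than the mitotic list on average, by 1.17 on the log2 scale, and the difference had this sign in each replicate pair (0.718, 0.527 and 2.28), but the 95% interval reaches 1.61 to either side over the arrays and 2.38 over the pairs. The lists therefore cannot be told apart here, although in pair 3 the epithelial mean was 0.374 higher. A direct effect of 4-hydroxytamoxifen cannot be told apart from that of the deletion either, as only deletion mice received it; estrogen-responsive genes had a camera adjusted p of 0.293, which does not exclude it.

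The rise of Col2a1 might come from cartilage in the dissections. The median change of the 7 other cartilage genes tested was 0.174, against 1.71, or 0.5 times the least change of Col2a1, but members went both ways. Col9a1 and Col9a2 lay 1.45 and 1.24 higher and passed with the replicate block (limma adjusted p = 0.00131 and 0.00544), and Col11a2, at 12.16 in control, would hide a small share. Cartilage therefore stays open, as do the deletion and the drug.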
